A study of Homo sapiens with 6 samples.

How the data were processed

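RNA was sequenced from the human gastric cancer lines HGC-27 and AGS, transduced with a lentivirus for NINJ1 overexpression or with a negative control. Per the labels' protocols, cells in 6-well plates were lysed in Trizol after 48 hours and libraries of polyadenylated RNA were made with a NEBNext Ultra kit. Each line had 1 control library and 2 NINJ1 libraries, 6 in all. Per the submitters' processing notes, HISAT2, HTSeq 0.13.5 and the genome build GRCh38 were used. No version of HISAT2, annotation release or strand setting was stated. Nothing in the labels says whether replicates were separate cultures or whether libraries were made on separate days.

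The deposited tables hold, per the file headers, a raw read count and an FPKM value for each of 51103 Ensembl genes, with 1 table per library. The deposited counts are whole numbers with a different total in each library. The authors' FPKM (a count scaled by gene length and library total) was checked against the counts: it equals the count divided by 1 fixed length per gene and by the library's total count, to a relative departure of at most 6.40e-09 for genes with at least 200 counts. Coordinates, gene types and GC content came from GENCODE release 29, in which all 51103 identifiers were found and 51091 symbols were the same. GC content is that of a gene's longest transcript.

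Total counts ran from 12619684 in AGS NINJ1 replicate 1 to 18175697 in the HGC-27 control. A count of 0 allows a true mean of up to 3 counts, so a fold against a group without any count was computed with 3 counts in each of its libraries and is given as a lower bound. These bounds cover counting error alone.

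Titles and file names put the 2 NINJ1 replicate 2 libraries in opposite lines. Before the data were examined, it was decided to run every comparison under both readings, titles and file names, and once more on the 4 libraries whose line is not in doubt. The 32 gene lists, the comparisons, the alternative settings and the rule for naming genes were also fixed before the data were examined. The count test applied edgeR 4.0.16 (R 4.3.3), planned for the case that the tables held counts. Genes were kept by filterByExpr with a minimum count of 10, which left 17617 genes (17208 in the 4-library comparison), and libraries were scaled by TMM. Quasi-likelihood F tests were two-sided, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. The standard error (SE) of a log2 change is its size divided by the square root of F.

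NINJ1 was compared with control over both lines with the line as an additive term. A model with 1 mean per line and treatment gave NINJ1 against control in each line and the difference between these contrasts. AGS was compared with HGC-27 with treatment as an additive term. In the model with 4 groups the spread comes from the 2 pairs of NINJ1 libraries, since each line has 1 control, and the control is assumed to vary like them. A difference from that control therefore includes whatever else set that library apart.

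Gene lists with at least 5 tested members (30 of 32) were tested with camera in limma 3.58.1, with a preset correlation between genes of 0.01 and again with an estimated correlation. The rotation test fry was run on each list alone. The ninjurin family and the blood cell markers had fewer tested members and are given as levels. List tests over both lines were planned. Those within each line were added after the data were seen. List members past the threshold are counted over all tested genes and also adjusted over the list alone.

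Genes were named by these rules: NINJ1 always; in the comparison over both lines, 8 genes per direction with the largest change past the threshold in which all 4 NINJ1 libraries lay on the same side of their line's control; 4 per direction for each line and for the difference; 6 per direction for AGS against HGC-27; and up to 3 members with the smallest p for each list described. Where no gene passed, the 3 with the smallest p per direction are given as values. Clone-type names were counted and not named. Other genes are marked as chosen after their values were seen.

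The alternatives chosen in advance were DESeq2 1.42.0 in place of edgeR, DESeq2's size factors in place of TMM, no filter, a mean FPKM of at least 5, pseudocounts of 0.1 and 0.5, FPKM rescaled to equal sums or divided by size factors, quantile normalisation, each library left out in turn, replicate number as a block, and Spearman in place of Pearson correlation. The FPKM alternatives were run with limma on log2(FPKM + 1), keeping genes with FPKM of at least 1 in at least 2 libraries. After the data were seen, limma on log2(FPKM + 1) without rescaling, a block with the replicate numbers crossed, and a GC correction were added. So were correlations of GC-corrected log2 CPM and a count, in the replicate 2 libraries, of genes with at least 100 counts in both undisputed libraries of a line and 0 in both of the other, taken as seen from 10 counts on. The GC correction removed from each library, through offsets, the lowess trend (span 0.3) of a gene's log2 CPM deviation on its GC content.

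The tests were tested on simulated data with 100 genes changed by each of 2 sizes. With the file-name lines, edgeR recovered 62% of 2-fold and 88% of 4-fold changes in AGS with 4 false calls, and 5% and 47% over both lines with 1 false call. It recovered 58% and 84% in HGC-27 with 3 false calls, 38% and 69% of differences between lines with 5, and 2% and 53% for AGS against HGC-27 with 2. In AGS limma recovered 49% and 86%, and DESeq2 42% and 77%, with 4 false calls each. Camera with either correlation and fry each recovered 5 of 5 shifted lists with 0 false calls among 30 lists. Simulated genes varied independently with a common spread and no GC trend, and every member of a shifted list was raised 2-fold. The simulation therefore cannot show how the list tests behave when genes are correlated.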

Results

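Messenger RNA was counted by sequencing in HGC-27, a line from an undifferentiated gastric carcinoma, and AGS, a line from a gastric adenocarcinoma. Both lines carried a lentivirus for NINJ1 overexpression or a negative control. NINJ1 (ninjurin-1, ENSG00000131669, GRCh38 chromosome 9, 93121489 to 93134288, minus strand) is a cell-surface adhesion protein that also ruptures the plasma membrane during lytic cell death. Each line had 1 control library and 2 NINJ1 libraries, and the cells were harvested after 48 hours. The total count was 18175697 in the HGC-27 control, 14482670 in HGC-27 NINJ1 replicate 1 and 13275233 in the NINJ1 replicate 2 titled HGC-27. It was 13948290 in the AGS control, 12619684 in AGS NINJ1 replicate 1 and 15045666 in the NINJ1 replicate 2 titled AGS. Genes with at least 1 count numbered 19371 in the HGC-27 control and between 22839 and 23396 in the other 5 libraries. Nothing in the labels says that replicates were separate cultures, so the p-values measure only the spread between these libraries.

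The first question was which line each library came from, because titles and file names gave opposite lines for the NINJ1 replicate 2 libraries. To decide without either reading, genes were chosen, after the data were seen, on the 4 libraries whose line is not in doubt. Of 15 genes with at least 100 counts in both such HGC-27 libraries and 0 in both of AGS, the replicate 2 titled AGS held at least 10 counts of 15 and the replicate 2 titled HGC-27 of 0. Of 13 genes with the reverse profile they held at least 10 counts of 0 and 13. The genes named next were picked from the comparison with file-name lines, so they follow those lines by choice. GPRIN3 had 12852, 3117 and 2437 counts in the HGC-27 control, HGC-27 NINJ1 replicate 1 and the replicate 2 titled AGS, and 0 in the other 3 libraries. The same 3 libraries held 11617, 2122 and 2335 counts of SRGN, the core protein of the serglycin proteoglycan, against 0, 2 and 0. They also held at least 420 counts each of MPDZ (a scaffold protein of tight junctions), EMB (embigin, a partner of monocarboxylate transporters), TSPAN6 (a tetraspanin) and the noncoding LINC02582, none of which had a count in the libraries named AGS. In reverse, PASD1 and MAGEA12 (cancer-testis antigens), WFDC1, C22orf34, QPRT (an enzyme of NAD synthesis) and GUCY1A2 (a subunit of soluble guanylate cyclase) had at least 134 counts in each library named AGS and 0 in each named HGC-27. Those 12 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at adjusted p from 0.00116 to 0.00746 (3 libraries per line), and no fold is given because a whole group is at or near 0. Without HGC-27 NINJ1 replicate 1 the calls of EMB and TSPAN6 ended (edgeR adjusted p = 0.0505 and 0.0542).

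**Figure D1:**
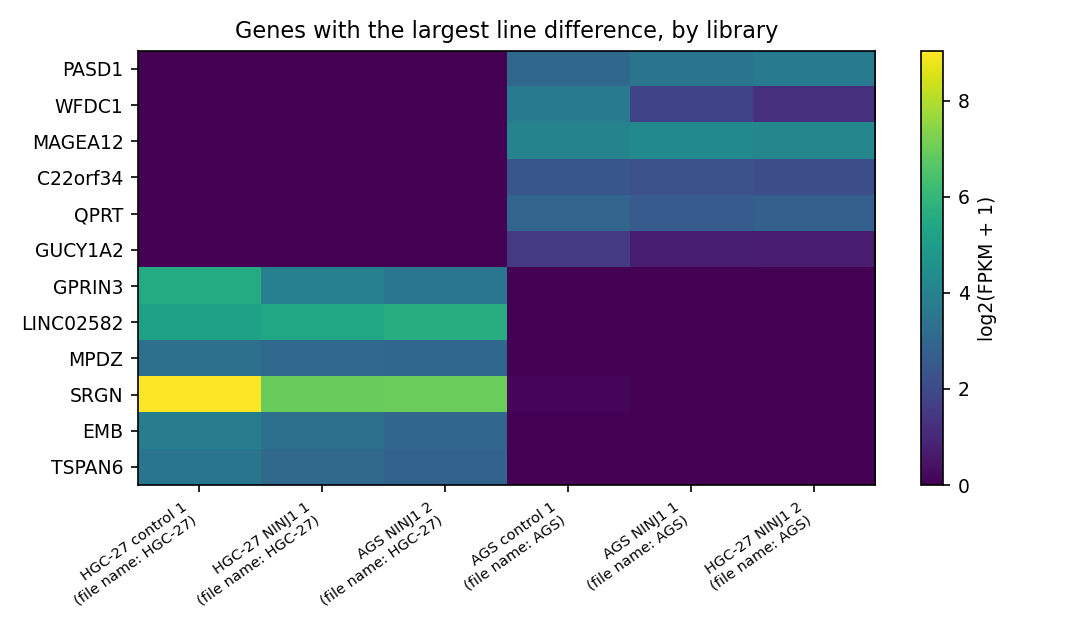
Heat map of log2(FPKM + 1) for the 12 genes with the largest difference between the lines, 1 column per library and 1 row per gene. The replicate 2 library titled AGS has 2437 counts of GPRIN3 and 0 of PASD1, and the replicate 2 library titled HGC-27 has 0 and 732.

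With lines as in the file names, 576 genes were higher and 506 lower in AGS than in HGC-27 among 17617 tested. Interferon-stimulated genes, which cells switch on against viruses, were the list that camera called: 12 of 22 were lower in AGS and 0 higher (14 and 0 adjusted over the list alone), with a median log2 difference of -1.71 (camera adjusted p = 4.74e-17, and adjusted p = 0.224 with an estimated correlation). Fry called 4 lists in this comparison, and 12 with the GC correction, with which camera still called 1. IFIT3, IFIH1 and IFI44 were lower by log2 -3.02 (SE 0.20), -3.18 (SE 0.24) and -3.46 (SE 0.28), with edgeR adjusted p of 0.00332, 0.00342 and 0.00440. The count of 1082 genes was 3866 with the GC correction and moved with each library left out: 7117 without the HGC-27 control, 7082 without the AGS control, 114 without HGC-27 NINJ1 replicate 1, 173 without AGS NINJ1 replicate 1, 190 without the replicate 2 titled HGC-27 and 186 without the replicate 2 titled AGS. With lines as titled, 0 genes passed with edgeR (52 at an unadjusted p under 0.05, where chance gives 881) and 0 with DESeq2. The genes with the smallest p under the titles were DEGS2 (log2 4.17, SE 1.34), GPR132 (4.63, SE 1.50) and GAL3ST2 (4.07, SE 1.40) upward and CASC1 (-3.50, SE 1.12), HSP90AA2P (-4.65, SE 1.65) and ZNF483 (-4.10, SE 1.50) downward, at an edgeR adjusted p of 0.834.

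Correlations of log2(FPKM + 1) across genes, which are not independent replicates, gave the same pairs where NINJ1 libraries were compared. The replicate 2 library titled HGC-27 had r = 0.991 with AGS NINJ1 replicate 1 and 0.950 with HGC-27 NINJ1 replicate 1. The replicate 2 library titled AGS had r = 0.989 with HGC-27 NINJ1 replicate 1 and 0.943 with AGS NINJ1 replicate 1. Against the controls, the library titled HGC-27 lay closer to the AGS control (0.972) than to the HGC-27 control (0.854), and the library titled AGS also lay closer to the AGS control (0.924 against 0.857). HGC-27 NINJ1 replicate 1, whose line is not in doubt, had r = 0.927 with the AGS control and 0.880 with its own. On log2 CPM after the GC correction described below, the direction turned for the library titled AGS and for HGC-27 NINJ1 replicate 1 and stayed for the library titled HGC-27. The library titled AGS then had r = 0.937 with the HGC-27 control and 0.910 with the AGS control, HGC-27 NINJ1 replicate 1 0.941 and 0.912, and the library titled HGC-27 0.892 and 0.972. On log2 CPM without the correction, the library titled AGS had r = 0.888 with the HGC-27 control and 0.908 with the AGS control. For HGC-27 NINJ1 replicate 1 these were 0.903 and 0.910, and for the library titled HGC-27 0.861 and 0.971. In what follows, each comparison is given for the file-name lines and then for the titles.

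Whether NINJ1 mRNA was raised was the next question. In HGC-27 it was 3.71-fold higher in the NINJ1 libraries than in the control, at a scaled CPM of 17.3 and 19.1 against 4.89 (log2 1.89, SE 0.24, 2 libraries against 1, edgeR adjusted p = 3.22e-08). With the GC correction described next, that difference was log2 0.58 (edgeR adjusted p = 0.0334). In AGS the libraries labelled NINJ1 held less NINJ1 mRNA than the control, at 19.5 and 15.9 CPM against 28.4 (log2 -0.68, SE 0.19, edgeR adjusted p = 0.0148), so NINJ1 level goes against the label there. The labels do not say whether the lentiviral NINJ1 carries the sequence counted for the gene; if it does not, every NINJ1 value here is that of the cell's own gene alone. Without the replicate 2 titled HGC-27 the AGS value was -0.54 (edgeR adjusted p = 0.260), and DESeq2 gave -0.70 (adjusted p = 0.136). The 2 lines' changes differed by log2 -2.57 (SE 0.31, edgeR adjusted p = 1.69e-08; -1.16 with the GC correction). Over both lines NINJ1 had log2 0.39 (SE 0.61, edgeR adjusted p = 0.739) for 4 NINJ1 libraries against 2 controls, and -0.066 with the GC correction (edgeR adjusted p = 0.904). Without the HGC-27 control the value was -0.68 (edgeR adjusted p = 0.0115) and without the AGS control 1.95 (edgeR adjusted p = 4.91e-09). AGS and HGC-27 did not pass for NINJ1 (log2 0.76, SE 0.57, edgeR adjusted p = 0.458). Its relative NINJ2 had 42 counts in the AGS control and 4 and 11 in the NINJ1-labelled libraries named AGS (log2 -2.42, SE 0.70, edgeR adjusted p = 0.0162), against 7, 2 and 6 in the libraries named HGC-27.

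**Figure D2:**
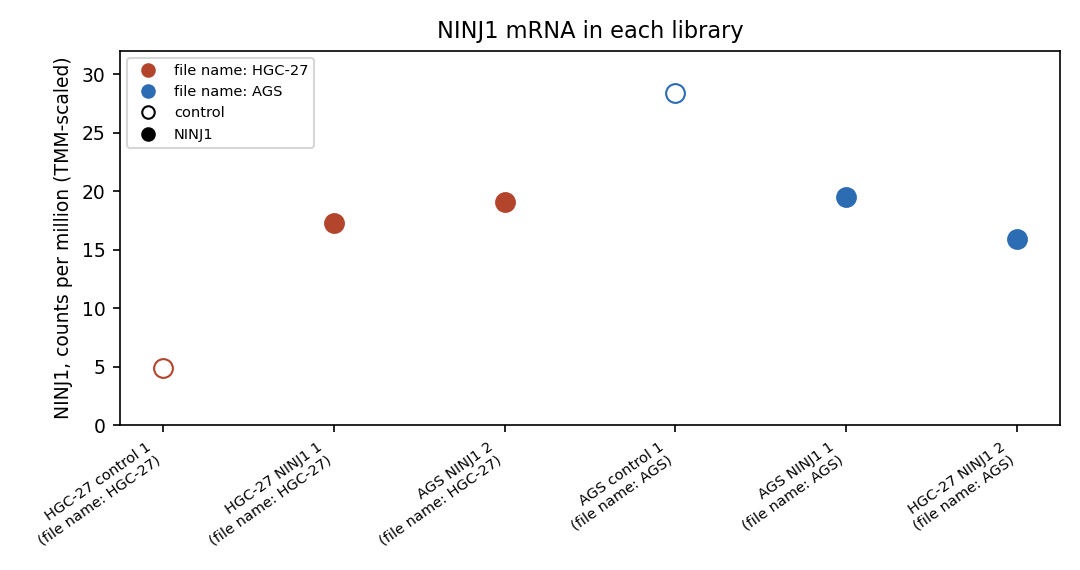
NINJ1 mRNA in TMM-scaled CPM (vertical axis), 1 point per library, open for controls and filled for NINJ1, coloured by the line in the file name. The control is the lowest of the HGC-27 libraries (4.89) and the highest of the AGS libraries (28.4).

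The HGC-27 control differed from the other 5 libraries in how transcript level depended on GC content. Genes with a GC content above 65% lay at a median log2 of -2.38 from their mean over the 6 libraries in that control, and those under 35% lay at 0.48. Medians of the other 5 libraries stayed between -0.30 and 0.78 over all GC classes. Genes above 60% GC gave 2.31% of the counts in the HGC-27 control and between 9.25% and 11.3% elsewhere. Mitochondrial-encoded genes gave 6.50% of counts in the HGC-27 control, 5.00% in the AGS control and 2.78% to 3.75% in the NINJ1 libraries. MT-CO1, a subunit of cytochrome c oxidase, took 3.68% of all counts in the HGC-27 control, 1.40% in the AGS control and between 0.727% and 1.07% in the others. Main values that compare with the HGC-27 control are therefore given also after a GC correction, added after the data were seen.

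**Figure D3:**
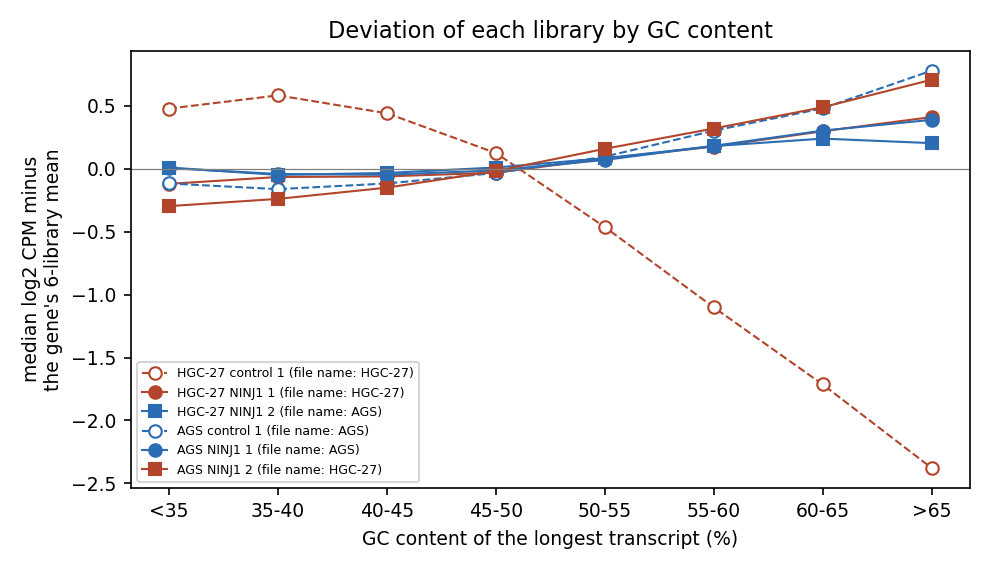
Median log2 CPM of tested genes minus each gene's mean over the 6 libraries (vertical axis) by GC content of the longest transcript in percent (horizontal axis), 1 line per library. The HGC-27 control runs from 0.48 under 35% to -2.38 above 65%, and the other 5 libraries stay between -0.30 and 0.78.

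What differed between the NINJ1-labelled libraries and the control in AGS was asked next, with the 2 libraries named AGS against 1 control. The NINJ1 level of these libraries was itself below the control's. HSP90AA1, the stress-inducible form of the chaperone HSP90, was 3.94-fold higher (log2 1.98, SE 0.14) and HSPA8, a constitutive HSP70 chaperone, 3.87-fold (1.95, SE 0.15). HSPH1, which recharges HSP70, was 2.60-fold higher (1.38, SE 0.14), DNAJB1, an HSP40 co-chaperone, 3.00-fold (1.58, SE 0.16) and HSPA1A, the inducible HSP70, 4.55-fold (2.19, SE 0.23). ALPI, intestinal alkaline phosphatase, was 23.7-fold lower (log2 -4.57, SE 0.16). MUC16, the mucin that carries the CA125 antigen, was 4.08-fold lower (-2.03, SE 0.13), the placental phosphatase ALPP 5.00-fold (-2.32, SE 0.15) and the collagen genes COL15A1 and COL5A1 4.25-fold (-2.09, SE 0.13) and 3.62-fold (-1.86, SE 0.12). WISP2, a secreted matricellular protein, was 7.38-fold lower (-2.88, SE 0.17), and RGS2, a brake on G-protein signalling, 3.29-fold higher (1.72, SE 0.18). The edgeR adjusted p of these 12 genes, named after their values were seen except the list members HSP90AA1, HSPA8, HSPH1 and COL5A1, ranged from 2.19e-20 to 1.75e-08.

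In AGS 1010 genes rose and 1638 fell in the NINJ1-labelled libraries with edgeR, 134 and 673 of them by more than 2-fold. The median GC content was 44.9% among genes called higher and 54.9% among those called lower, and with the GC correction 1498 rose and 1795 fell. The largest changes were in genes with few counts. ECEL1 (a metalloprotease-family protein) was at least 11.2-fold lower, with 35 counts in the control and 0 in both other libraries, CROCC2 at least 6.10-fold, and MYO1A (a brush-border myosin) and the histone gene HIST2H3D at least 4.17-fold. SORCS1 (a sorting receptor) was at least 3.98-fold higher, BACH2 (a transcription repressor of lymphocytes) at least 2.74-fold and LCP1 (plastin-2, an actin bundler with 11738 to 18062 counts in the libraries named HGC-27) at least 2.59-fold. The pseudogene ASLP1 had 1 count in the control and 30 and 6. None of these 8 passed with DESeq2. Without the replicate 2 titled HGC-27 the calls of SORCS1, BACH2, CROCC2, MYO1A and HIST2H3D ended (edgeR adjusted p = 0.106, 0.170, 0.0532, 0.0865 and 0.118), and without AGS NINJ1 replicate 1 those of SORCS1, ASLP1, MYO1A and HIST2H3D (0.0714, 0.453, 0.0616 and 0.0875). The count of 2648 was 935 without the replicate 2 titled HGC-27 (21.5% up against 38.1%), 1438 without AGS NINJ1 replicate 1, 4712 without HGC-27 NINJ1 replicate 1 and 4702 without the replicate 2 titled AGS. DESeq2 called 1308. Limma on FPKM rescaled to equal sums, where the median of all genes was 0.19 (0.00 with edgeR), called 1289 up and 460 down, and on FPKM divided by size factors 237 up and 710 down.

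Gene lists gave the AGS change its shape, again with NINJ1 itself below the control. Among heat shock and proteotoxic stress genes 13 of 16 rose and 0 fell (14 and 1 adjusted over the list alone; median log2 0.98, camera adjusted p = 2.38e-17, and adjusted p = 0.319 with an estimated correlation). Of mitochondrial-encoded genes 12 of 13 fell (12 adjusted over the list alone), with a median of -0.74 that was 0.00 under quantile normalisation (camera adjusted p = 1.64e-12, and adjusted p = 0.319 with an estimated correlation). Quantile normalisation gives the highest-ranked genes the same values in every library, so it cannot show a fall there. The other FPKM scalings gave medians of -0.57 to -0.78. MT-ND4L, MT-CO1 and MT-CO3, subunits of the respiratory chain, fell by 0.95 (SE 0.13), 0.89 (SE 0.12) and 0.93 (SE 0.13) on the log2 scale. Nuclear respiratory chain genes had 0 of 22 past the threshold in either direction, also adjusted over the list alone. Their smallest p belonged to NDUFB9 (0.35, SE 0.15), UQCRC1 (-0.28, SE 0.12) and UQCRQ (-0.34, SE 0.17). Without HGC-27 NINJ1 replicate 1 those 3 genes passed (edgeR adjusted p = 0.0121, 0.00952 and 0.0347), as they did without the replicate 2 titled AGS (0.0119, 0.00894 and 0.0359). Histone genes had 5 of 15 lower and 0 higher (the same adjusted over the list alone, camera adjusted p = 4.91e-05, and adjusted p = 0.319 with an estimated correlation). Among them were HIST2H2BE (-2.76, SE 0.27) and HIST1H2AC (-1.98, SE 0.27). Under the 4 FPKM scalings limma called 9 to 13 heat shock genes higher, 4 histone genes lower, and 1 to 6 mitochondrial-encoded genes lower with 1 higher under quantile normalisation. With the GC correction camera called 19 lists in AGS against 17 without (0 of either with an estimated correlation).

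Several marker lists were called lower by camera in the NINJ1-labelled AGS libraries. Most endothelial and fibroblast markers, and most gastric and intestinal markers, were near the floor (median FPKM of 0.05 each in the AGS control). In that control 3 of 16 and 5 of 24 listed genes had an FPKM of at least 1. Mesenchymal markers had 9 of 19 lower and 1 higher (10 and 2 adjusted over the list alone; median -0.57, camera adjusted p = 2.62e-07, and adjusted p = 0.319 with an estimated correlation). Leading them were COL5A1, S100A4 (a calcium-binding motility protein, -1.52, SE 0.14) and TGFBI (a matrix protein, -1.60, SE 0.15). Epithelial markers had 5 of 16 lower and 0 higher (6 and 0 adjusted over the list alone; median -0.51, camera adjusted p = 3.02e-06, and adjusted p = 0.327 with an estimated correlation). They included the junction genes TJP3 (-3.55, SE 0.25) and CLDN7 (-1.61, SE 0.22) and the epithelial transcription factor ELF3 (-1.09, SE 0.14). Cell adhesion and integrin genes had 7 of 17 lower and 0 higher (9 and 2 adjusted over the list alone; median -0.34, camera adjusted p = 0.000334, and adjusted p = 0.319 with an estimated correlation), with the laminin LAMA5 (-1.10, SE 0.13) and the integrins ITGB4 (-0.99, SE 0.13) and ITGA1 (-1.02, SE 0.14). Endothelial and fibroblast markers had 5 of 8 lower (6 adjusted over the list alone; median -2.42, or -1.88 with bounds, camera adjusted p = 3.24e-06, and adjusted p = 0.319 with an estimated correlation), with PDGFRB (-2.45, SE 0.26), COL1A1 (-1.36, SE 0.16) and EGFL7 (-0.89, SE 0.16). Gastric and intestinal markers had 3 of 11 lower (4 adjusted over the list alone, camera adjusted p = 0.0137, and adjusted p = 0.319 with an estimated correlation), their median being -0.13 and 0.05 on FPKM rescaled to equal sums. Among them were the mucins MUC1 (-1.70, SE 0.14) and MUC5AC (-0.98, SE 0.31, edgeR adjusted p = 0.0307, and 0.442 without the replicate 2 titled HGC-27) and the transcription factor HNF4A (-2.67, SE 0.28). Limma on FPKM called 6 or 7 mesenchymal, 3 epithelial, 5 or 6 cell adhesion, 2 endothelial and fibroblast and 2 gastric genes lower over its 4 scalings, and 2 cell adhesion genes higher on FPKM rescaled to equal sums.

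Camera called further lists in AGS. Interferon-stimulated genes had 7 of 22 lower (7 adjusted over the list alone; median -0.27, camera adjusted p = 0.000799, and adjusted p = 0.319 with an estimated correlation). With the lines as titled their median was instead 0.55 and the list was not called (camera adjusted p = 0.0915, and adjusted p = 0.899 with an estimated correlation). Examples with the file-name lines are ISG15 (-1.22, SE 0.16), OASL (-1.25, SE 0.17) and IFIT1 (-1.16, SE 0.18). Antigen presentation genes had 8 of 15 lower and 1 higher (10 and 1 adjusted over the list alone; median -0.62, camera adjusted p = 0.00100, and adjusted p = 0.336 with an estimated correlation). B2M (-0.64, SE 0.12) was lower and the peptide transporter TAP2 (0.74, SE 0.15) higher. Mitosis genes had 6 of 22 higher and 0 lower (6 adjusted over the list alone; median 0.23, camera adjusted p = 0.00110, and adjusted p = 0.336 with an estimated correlation). The calls of BUB1 (0.45, SE 0.13), PLK1 (0.47, SE 0.14) and BIRC5 (0.46, SE 0.14) ended without the replicate 2 titled HGC-27 (edgeR adjusted p = 0.233, 0.312 and 0.249) and without AGS NINJ1 replicate 1 (0.134, 0.0771 and 0.146). DNA replication genes had 4 of 22 lower and 0 higher (9 and 0 adjusted over the list alone; median -0.28, camera adjusted p = 0.00129, and adjusted p = 0.319 with an estimated correlation). The helicase subunit MCM5 was lower by log2 -0.87 (SE 0.15). Hypoxia response genes had 7 of 20 lower and 1 higher (9 and 1 adjusted over the list alone; median -0.27, camera adjusted p = 0.00200, and adjusted p = 0.336 with an estimated correlation). TGF-beta targets had 6 of 18 lower (8 adjusted over the list alone; median -0.28, camera adjusted p = 0.00200, and adjusted p = 0.319 with an estimated correlation). ANGPTL4, a secreted lipase inhibitor (-1.02, SE 0.17), and ID3, a transcription inhibitor (-1.46, SE 0.22), are examples from these lists. Ribosomal proteins (3 of 25 lower, 3 adjusted over the list alone; median -0.21), glycolysis (7 of 20 lower, 7 adjusted over the list alone; median -0.21) and cholesterol biosynthesis (5 of 23 lower and 2 higher, 7 and 2 adjusted over the list alone; median -0.23) were also called by camera, at adjusted p = 0.00492, 0.00612 and 0.0468. With an estimated correlation, adjusted p = 0.517, 0.427 and 0.523. Under the 4 FPKM scalings limma called fewer members: 0 to 5 mitosis genes higher, and lower 6 interferon-stimulated, 2 to 4 antigen presentation, 0 to 2 DNA replication, 2 to 5 hypoxia, 2 to 4 TGF-beta, 1 or 2 glycolysis, 2 cholesterol and 0 ribosomal protein genes.

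The lytic cell death list, to which NINJ1's known function is closest, was not called in AGS (2 of 15 higher and 2 lower, the same adjusted over the list alone, camera adjusted p = 0.711). IL18, a cytokine released through membrane pores, fell by 1.61 on the log2 scale (SE 0.17, edgeR adjusted p = 1.19e-08) and the pore former GSDME by 0.73 (SE 0.15, edgeR adjusted p = 0.000551). The inflammatory caspase CASP4 rose by 0.65 (SE 0.16, edgeR adjusted p = 0.00401, and 0.122 without the replicate 2 titled HGC-27). The other 11 uncalled lists with any member past the threshold were fatty acid metabolism (0 higher and 3 lower of 22), matrix proteases (0 and 3 of 19), NF-kB (1 and 5 of 19), ATF4 targets (4 and 5 of 20), endoplasmic reticulum chaperones (0 and 4 of 20), apoptosis regulators (4 and 1 of 20), Wnt targets (1 and 2 of 16), YAP targets (2 and 4 of 18), p53 targets (3 and 1 of 24), immediate-early genes (2 and 4 of 23) and NRF2 genes (5 and 5 of 21). Adjusted over the list alone these were 0 and 3, 2 and 3, 3 and 5, 8 and 5, 0 and 4, 5 and 1, 2 and 3, 3 and 4, 3 and 2, 4 and 4, and 6 and 5. Blood cell markers stayed near the floor, with at most 2 of 15 genes at an FPKM of 1 or more in any library.

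**Figure D4:**
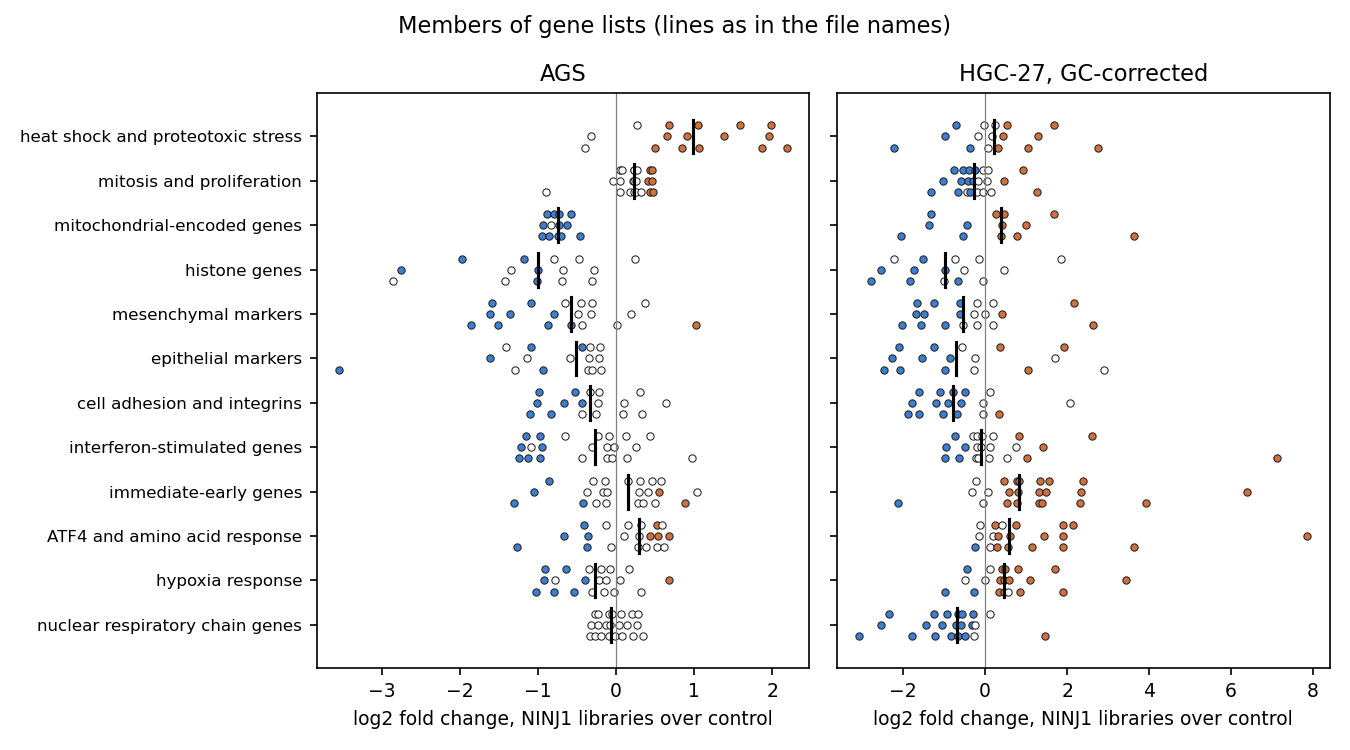
Log2 fold change of each tested member (points) of 12 gene lists, NINJ1-labelled libraries over control, in AGS and in HGC-27 after GC correction; orange and blue fill mark members called higher and lower, and black bars are medians. Heat-shock genes lie to the right in AGS (median 0.98) and mitochondrial-encoded genes to the left (-0.74, and 0.00 under quantile normalisation, which equalises the highest-ranked genes), while immediate-early genes lie to the right in HGC-27 (0.83).

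In HGC-27 the same question was asked of HGC-27 NINJ1 replicate 1 and the replicate 2 titled AGS against 1 control, the control whose GC profile stood apart. Immediate-early genes, the first to respond to stimulation, rose: 19 of 23 were higher and 0 lower (the same adjusted over the list alone; median log2 2.21, or 1.89 with bounds, camera adjusted p = 4.36e-06, and adjusted p = 0.618 with an estimated correlation). After the GC correction 18 were higher and 1 lower with a median of 0.83. FOSB, a subunit of the AP-1 transcription factor, was 13.2-fold higher (log2 3.72, SE 0.25; 2.33 with the GC correction), IER3 8.47-fold (3.08, SE 0.17; 1.55) and IER2 10.8-fold (3.43, SE 0.24; 1.39). ATF4 and amino acid response genes had 17 of 20 higher and 1 lower (the same adjusted over the list alone; median 1.61, camera adjusted p = 4.96e-06, and adjusted p = 0.618 with an estimated correlation). After the correction these were 14 and 1 with a median of 0.58. STC2, a secreted stress glycoprotein, was 5.13-fold higher (2.36, SE 0.15; 1.89 with the GC correction), DDIT4, an inhibitor of mTORC1, 10.4-fold (3.38, SE 0.22; 1.90), and the amino acid transporter SLC7A5 4.57-fold (2.19, SE 0.14; 0.25). Nuclear respiratory chain genes had 16 of 22 lower and 5 higher (the same adjusted over the list alone; median -0.91, camera adjusted p = 0.00174, and adjusted p = 0.618 with an estimated correlation). After the correction these were 18 and 1 with a median of -0.70. ATP5PO of the ATP synthase was lower by log2 -2.94 (SE 0.20; -2.53 with the GC correction), NDUFS6 of complex I by -1.54 (SE 0.13; -2.34) and SDHB of complex II by -1.43 (SE 0.13; -1.45). The edgeR adjusted p of these 9 genes was at most 8.67e-12.

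Other genes of stress and metabolism stood out in HGC-27. Hypoxia response genes had 13 of 20 higher and 3 lower (the same adjusted over the list alone; median 0.97, 0.46 with the GC correction, camera adjusted p = 0.0242, and adjusted p = 0.618 with an estimated correlation). They included ANGPTL4 (4.01, SE 0.21; 1.69 with the GC correction) and the glucose transporter SLC2A1 (2.04, SE 0.14; 1.09). Mitosis genes had 15 of 22 lower and 5 higher (16 and 5 adjusted over the list alone; median -0.76, camera adjusted p = 0.0204, and adjusted p = 0.618 with an estimated correlation). That call ended with the GC correction (11 lower and 3 higher, median -0.27, camera adjusted p = 0.127). AURKB, a mitotic kinase, was higher (2.35, SE 0.20; 1.28) where CENPF and KIF11 were lower (-1.65 and -1.36, SE 0.12 each; -1.03 and -0.66). FTH1, the ferritin heavy chain, was 18.5-fold higher (4.21, SE 0.23; 3.96), and HSPA1B, an inducible HSP70, 20.0-fold (4.33, SE 0.25; 2.75), although heat shock genes as a list had 7 higher and 7 lower of 16 (the same adjusted over the list alone, camera adjusted p = 0.787). IL18 was lower by log2 -2.79 (SE 0.17; -2.10 with the GC correction), as was CASP1, which activates it, by -1.81 (SE 0.18; -1.20), while the sensor NLRP1 was higher by 2.47 (SE 0.21; 1.48). The lytic cell death list had 4 higher and 10 lower of 15 (the same adjusted over the list alone, camera adjusted p = 0.144). Each gene in this paragraph had an edgeR adjusted p of at most 1.14e-10 before the correction. The median FPKM of hypoxia genes was 7.33 in the HGC-27 control, 22.3 in the AGS control and 18.3 to 21.3 in NINJ1 libraries. The hypoxia difference, too, rests on a control unlike that of the other line.

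Over all 17617 genes, 5985 were higher and 5118 lower in the NINJ1 libraries named HGC-27 than in the control with edgeR, and 4017 and 4654 after the GC correction. The median GC content was 57.4% among genes called higher and 41.8% among those called lower. The rule for the largest changes named CTU1 (a tRNA thiolation enzyme), SPATA2L, LRP3 and NFKBID (a nuclear IkB protein), which had 0 counts in the HGC-27 control and were at least 103, 91.4, 77.0 and 74.0-fold higher. These bounds rest on the control whose GC profile stood apart, so they cannot be told apart from loss in that library. PZP (a protease inhibitor) was at least 9.98-fold lower, AKR1B10 (an aldo-keto reductase) 8.20-fold, and the pseudogene NDUFB1P2 and the antisense transcript AQP4-AS1 7.13-fold, each with 0 counts in both NINJ1 libraries. DESeq2 did not call the last 2. Genes chosen after their values were seen, for the smallest p, included NR4A1 (an immediate-early nuclear receptor; log2 4.62, SE 0.20; 2.88 with the GC correction), TNFRSF12A (the TWEAK receptor; 5.43, SE 0.24; 2.98) and MSLN (mesothelin; 4.55, SE 0.19; 1.91). Lower were MUC16 (-2.67, SE 0.12; -2.94), STS (steroid sulfatase; -3.12, SE 0.14; -2.64) and SPINK5 (a protease inhibitor; -3.34, SE 0.15; -2.91). Limma on log2(FPKM + 1) called 8431 genes, 70.7% of them higher against 53.9% with edgeR, with a median of all genes of 0.32 (0.12 with edgeR), and limma on FPKM rescaled to equal sums 71.5% of 8575 with a median of 0.39. Under quantile normalisation, with a median of -0.16, 43.4% of 8682 were higher.

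The lists that camera called in HGC-27 after the GC correction alone were mostly lower, while without it the medians of the DNA replication, epithelial, cell adhesion, ribosomal and gastric lists took the opposite sign under 1 to 3 of 5 scalings. Camera adjusted p of these 11 lists ranged from 2.16e-05 to 0.0380 with the correction, and with an estimated correlation no list had an adjusted p under 0.305. DNA replication genes had 16 of 22 lower and 0 higher with the correction (median -0.48) against 11 and 7 without. Cell adhesion genes had 12 of 17 lower and 1 higher (median -0.79) against 7 and 5, fatty acid metabolism 14 of 22 lower and 2 higher against 12 and 4, ribosomal proteins 16 of 25 lower and 4 higher against 11 and 8, and histone genes 7 of 15 lower and 0 higher against 5 and 2. Mesenchymal markers (9 of 19 lower and 3 higher against 10 and 6), epithelial markers (8 of 16 lower and 3 higher against 4 and 5), glycolysis (11 of 20 lower and 4 higher against 5 and 7) and gastric markers (5 of 11 lower and 0 higher against 3 and 4) were called lower too. Higher with the correction were p53 targets (12 of 24 and 3 lower, against 12 and 6), with PHLDA3, an inhibitor of AKT, at log2 6.27 (SE 0.38; 4.58 with the correction), and apoptosis regulators (11 of 20 and 2 lower, against 11 and 4). Adjusted over the list alone these counts were the same except, with the correction, 18 DNA replication genes lower and 4 epithelial markers higher and 8 lower. The direction turned with the correction for 10 of the list members with the smallest p, among them KRT7 (log2 1.25, then -0.99), MMP15 (1.88, then -0.86), FASN (2.04, then -0.59) and HLA-C (1.69, then -0.53).

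The comparison set in advance as the main one was over both lines, with 4 NINJ1-labelled libraries against 2 controls. NINJ1 mRNA was below control in the 2 of them named AGS. In this model a change that differs in size between the lines counts as spread. With file-name lines its biological coefficient of variation was 0.378, against 0.101 in the 4-group model. A gene that changed in both lines by unequal amounts can therefore fail here. With the other line's control left out, MUC16 had log2 -2.02 in AGS and -2.62 in HGC-27, and DNAJB1 1.59 and 2.03. No gene passed with edgeR (2257 at an unadjusted p under 0.05, where chance gives 881), DESeq2 called 312 (68 higher and 244 lower), and limma called 0, with a median of all genes of 0.19 on log2(FPKM + 1) and 0.30 on FPKM rescaled to equal sums (0.03 with edgeR). The smallest p upward belonged to the co-chaperone DNAJB1 (log2 1.78, SE 0.24, edgeR adjusted p = 0.222; 1.45 with the GC correction), HSPA1A (2.04, SE 0.33, edgeR adjusted p = 0.249; 1.11) and QRICH2 (1.79, SE 0.30, edgeR adjusted p = 0.249; 1.26). Downward it belonged to MUC16 (-2.36, SE 0.21; -2.52 with the GC correction), MAOB, which degrades monoamines (-1.84, SE 0.20; -1.86), and AKR1C1, a steroid-metabolising reductase (-3.40, SE 0.38; -2.92), each at an edgeR adjusted p of 0.222 before it. After the GC correction 57 genes were higher and 270 lower. Those named by the rule included HSPA1B (2.34, edgeR adjusted p = 0.0158), SOCS2, a brake on cytokine signalling (1.64, edgeR adjusted p = 0.0259), ALPI (-4.58, edgeR adjusted p = 0.00377), the mucin MUC5B (-3.60, edgeR adjusted p = 0.0214) and C4BPA, a complement inhibitor (-3.57, edgeR adjusted p = 0.00960). The others were GPAT3, FAM241B, NFKBIB, ZDHHC11, DOHH and IL1RL1 upward and NPY4R, P2RX1, CSPG4P13, HIST2H2BF and SORBS2 downward. Uncorrected changes, with the other line's control left out, were unequal between the lines for several of these. DOHH had log2 0.81 in AGS and 5.15 in HGC-27, NFKBIB 1.15 and 3.96, and ZDHHC11 1.00 and 3.27. HIST2H2BF had the larger change in AGS (-3.95 and -2.40), and GPAT3 had 1.84 in each line. Without the HGC-27 control the uncorrected count was 2719, and without the AGS control 11043, since each reduces to 1 line.

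Camera called 12 of 30 lists over both lines while 0 of their members passed edgeR's test over all genes. Heat shock (median 0.50; adjusted p = 0.000135), ATF4 (0.69; adjusted p = 4.82e-05) and immediate-early genes (0.90; adjusted p = 9.99e-05) were higher. Histone (-0.71; adjusted p = 4.82e-05), mitochondrial-encoded (-0.40; adjusted p = 9.93e-05), mesenchymal (-0.31; adjusted p = 0.00106), endothelial and fibroblast (-1.57; adjusted p = 0.00137), nuclear respiratory chain (-0.55; adjusted p = 0.00861), fatty acid (-0.36; adjusted p = 0.0212), ribosomal protein (-0.22; adjusted p = 0.0263), cell adhesion (-0.32; adjusted p = 0.0263) and DNA replication genes (-0.29; adjusted p = 0.0474) were lower in camera, but of 5 scalings 4 turned the sign of the endothelial and fibroblast median, 3 that of the ribosomal and 1 each that of the mitochondrial-encoded and DNA replication medians. With an estimated correlation the smallest adjusted p was 0.343, and fry called 3 lists. With the GC correction camera called 17 lists (4 higher and 13 lower), at a smallest adjusted p of 0.186 with an estimated correlation, and fry 8. Without the correction, adjusted over the list alone, 4 heat shock genes were higher, and 6 mesenchymal, 4 mitochondrial-encoded, 2 histone, 2 endothelial and fibroblast and 1 cell adhesion genes were lower. Without the AGS control 5 lists were called.

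Whether the change differed between lines was tested directly, and 9547 genes passed with edgeR (4219 with a higher change in AGS and 5328 with a lower one; 6226 with the GC correction). Immediate-early genes (18 of 23 lower in AGS than in HGC-27 and 1 higher, camera adjusted p = 1.41e-05) and ATF4 genes (15 of 20 lower and 1 higher, camera adjusted p = 0.000291) had the smallest camera p as lists. Hypoxia response (12 of 20 lower and 2 higher, camera adjusted p = 0.00157), antigen presentation (10 of 15 lower and 2 higher; 0.0142), mitosis (14 of 22 higher and 4 lower; 0.00157) and nuclear respiratory chain genes (15 of 22 higher and 3 lower; 0.00291) were also called by camera, and with an estimated correlation adjusted p = 0.703 for all 6. Adjusted over the list alone the counts were 18 and 1, 16 and 1, 12 and 2, 11 and 2, 14 and 4, and 15 and 3. Without the GC correction the median change of immediate-early genes was 0.15 in AGS and 2.21 in HGC-27. That of ATF4 genes was 0.29 and 1.61. These list differences thus come mostly from the HGC-27 control, whose median FPKM in both lists was below that of every other library. They cannot be told apart from whatever else set that control apart. With the GC correction camera called 13 lists, 6 with a higher change in AGS and 7 with a lower one, none at an adjusted p under 0.496 with an estimated correlation. Immediate-early (13 lower and 1 higher), ATF4 (11 and 2), hypoxia (13 and 1), mitosis (13 higher and 3 lower) and nuclear respiratory chain genes (14 and 1) were among them. Adjusted over the list alone these were 15 and 1, 11 and 3, 13 and 1, 13 and 3, and 15 and 1. Antigen presentation was not called (5 lower and 1 higher, also adjusted over the list alone, camera adjusted p = 0.319). The genes with the largest differences had 0 counts in a group: CTXN1 had 0 in the HGC-27 control, 214 and 249 in the NINJ1 libraries named HGC-27, 290 in the AGS control and 96 and 94 in those named AGS. PLXNB3, a semaphorin receptor, had 0, 197 and 224 in HGC-27 and 215, 114 and 80 in AGS. The GC content of CTXN1 and PLXNB3 is 72.8% and 65.1%. Genes above 65% lay lowest in the HGC-27 control (median log2 -2.38). With the GC correction the 2 differences were log2 -11.35 and -11.13. Limma on log2(FPKM + 1) had 30.6% of 7047 genes with a higher change in AGS, against 44.2% with edgeR, with a median of all genes of -0.25 (-0.15 with edgeR), and quantile normalisation 56.5% of 7283 with a median of 0.20.

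With the lines as titled, the spread within groups was larger (biological coefficient of variation 0.414 against 0.101 for the file-name lines in the 4-group model). By the genes that separate the undisputed libraries, each titled NINJ1 pair holds a library with the HGC-27 profile and another with the AGS profile. Values by titles are therefore comparisons in which the line profiles are mixed. In HGC-27 as titled, 1615 genes were higher and 534 lower in the NINJ1 libraries, and 0 passed after the GC correction (3701 at an unadjusted p under 0.05). Without that correction DESeq2 called 4160 genes and limma under quantile normalisation 120. SPATA2L was at least 96.7-fold higher, LRP3 at least 86.1-fold, AMH, anti-Mullerian hormone, at least 59.6-fold and CTU1 at least 58.4-fold, each with 0 counts in the control whose GC profile stood apart. Lower were C4BPA (log2 -4.14, SE 0.66, edgeR adjusted p = 0.0341), the potassium channel KCNH5 (-4.47, SE 0.84, edgeR adjusted p = 0.0426), PALMD (-3.62, SE 0.54, edgeR adjusted p = 0.0332) and the transcription factor ZBTB20 (-3.17, SE 0.42, edgeR adjusted p = 0.0322). That count of 2149 was 0 without HGC-27 NINJ1 replicate 1, without AGS NINJ1 replicate 1 or without either replicate 2 library, and NINJ1 had log2 1.76 (SE 0.34, edgeR adjusted p = 0.0438), or 0.52 with the GC correction (SE 0.31, edgeR adjusted p = 0.391). Immediate-early genes (7 of 23 higher, camera adjusted p = 0.000173), ATF4 genes (6 of 20 higher; 0.000173) and nuclear respiratory chain genes (5 of 22 lower; 0.000251) were called as lists, each at adjusted p = 0.665 with an estimated correlation. After the GC correction camera called these 3 and 5 more, 3 higher and 5 lower in all (smallest adjusted p = 0.487 with an estimated correlation).

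In AGS as titled no gene passed with edgeR (595 at an unadjusted p under 0.05, where chance gives 881). DESeq2 called 27 genes and limma 0. NINJ1 had log2 -0.56 (SE 0.30, edgeR adjusted p = 0.884), again against the label. HSPH1 (1.36, SE 0.23), DNAJB1 (1.79, SE 0.34) and MTF1, the metal-response transcription factor (1.20, SE 0.27), had the smallest p upward, and ALPP (-2.35, SE 0.25), the carboxypeptidase CPM (-1.64, SE 0.24) and SNED1 (-2.20, SE 0.33) downward, at an edgeR adjusted p of 0.884. Heat shock genes were called higher as a list (median 1.20, camera adjusted p = 2.44e-13, and adjusted p = 0.487 with an estimated correlation). Camera called 8 lists lower: histone and mesenchymal (adjusted p = 1.35e-06 each), mitochondrial-encoded (adjusted p = 2.34e-06), cell adhesion (adjusted p = 0.000387), endothelial and fibroblast (adjusted p = 0.00143), TGF-beta (adjusted p = 0.0103), and glycolysis and epithelial genes (adjusted p = 0.0499 each). With an estimated correlation adjusted p = 0.570 for the epithelial list and adjusted p = 0.487 for the other 7. No member of the 9 lists passed with edgeR over all genes, and adjusted over the list alone 2 heat shock genes were higher and 3 mesenchymal genes lower. Over both lines as titled 0 genes passed with edgeR (1060 at an unadjusted p under 0.05; DESeq2 53; limma 0), and 2209 passed without the AGS control. The smallest p belonged to DNAJB1 (1.79, SE 0.29), HSPA1B (3.07, SE 0.59) and SMG5 (1.49, SE 0.32) upward and CPM (-2.06, SE 0.28), C4BPA (-3.74, SE 0.55) and MAOB (-1.83, SE 0.28) downward, at an edgeR adjusted p of 0.700. NINJ1 had log2 0.43 (SE 0.60, edgeR adjusted p = 0.837; 1.82 without the AGS control, edgeR adjusted p = 0.0412), and -0.037 with the GC correction. Camera called 12 lists with 0 at an estimated correlation (smallest adjusted p = 0.344 with an estimated correlation) and 3 lists without the AGS control. It called 17 with the GC correction (smallest adjusted p = 0.257 with an estimated correlation).

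The difference between the lines as titled had 0 genes past the threshold with edgeR (4459 at an unadjusted p under 0.05; DESeq2 2203; limma on log2(FPKM + 1) 0). ESRRA, an orphan nuclear receptor (log2 -5.42, SE 0.37; -3.16 with the GC correction), YDJC (-6.58, SE 0.46; -3.77) and the lactate transporter SLC16A3 (-4.64, SE 0.33; -2.48) had the smallest p downward. TMTC3 (2.49, SE 0.35; 1.93 with the GC correction), the redox protein TXN (2.10, SE 0.32; 1.65) and NDUFS5 of complex I (2.01, SE 0.31; 2.03) had the smallest upward. The edgeR adjusted p of these 6 genes was 0.0681 to 0.0702, and 0.335 with the GC correction. Camera called 5 lists for this difference, each at adjusted p = 0.715 with an estimated correlation. Nuclear respiratory chain (adjusted p = 0.00206), heat shock (adjusted p = 0.0194) and mitosis genes (adjusted p = 0.0377) had a higher change in AGS in camera, and immediate-early (adjusted p = 0.00206) and ATF4 genes (adjusted p = 0.00332) a lower one. Members past the threshold were 0 with edgeR, and adjusted over the list alone 2, 4 and 0 higher and 5 and 5 lower. Between the lines as titled, camera called immediate-early (adjusted p = 0.00348) and ATF4 genes (adjusted p = 0.0154) higher in AGS, each at adjusted p = 0.852 with an estimated correlation and with 0 members past the threshold, also adjusted over the list alone. With the GC correction camera called 0 lists higher in AGS and 1 lower. On the 4 libraries whose line is not in doubt, 1 gene of 17208 passed, ALPI, lower by log2 -3.91 in the NINJ1 libraries (SE 0.74, edgeR adjusted p = 0.00255; 593 genes at an unadjusted p under 0.05). At an unadjusted p under 0.05 chance alone would give 860 genes. DESeq2 called 4 in these libraries and limma on log2(FPKM + 1) 0. NINJ1 had log2 0.62 (SE 0.78, edgeR adjusted p = 1) in those 4 libraries, or 0.051 with the GC correction.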

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

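The tests of the control difference on GC content, of an exchange within AGS, of the replicate 2 libraries and of the other splits were chosen after their results were seen. Those of GC content as the whole cause, of a shared response and of NINJ1 among similar genes were written before. The gene differences here, with the file-name lines, passed edgeR's test of whether the change from control to NINJ1 differs between the lines. The placement of the replicate 2 libraries came from the conflict between titles and file names.

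The first pattern is that the HGC-27 control differs from the NINJ1 libraries named HGC-27 in most genes. In their change 9547 genes differ between the lines, a difference that the AGS change enters as well. A mean trend on GC content in each library is not the whole of it, since 8671 genes passed in HGC-27 after the GC correction. Loss that varies between genes of like GC content is not removed by that correction, so it is not excluded. Neither is a response common to both lines the whole of it, since the GC-corrected changes in the 2 lines had r = 0.0669 across genes. A part may come from GC-dependent loss in that control, because the difference between the 2 controls, without any NINJ1 library, had a Spearman rho of -0.587 with GC content, against 0.120 for the same difference between NINJ1 libraries. A batch difference between this control and the other libraries cannot be told apart from the treatment, since the line has 1 control. A response in HGC-27 alone stays open and was not tested.

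The next pattern is NINJ1 mRNA itself, whose change differed between the lines by log2 -2.57, higher than control in HGC-27 and lower in AGS. An exchange of the control with an NINJ1 library within AGS is argued against, because the NINJ1-labelled libraries named AGS had r = 0.991 with each other and at most 0.976 with the control, a gap of 0.0154. The rise in HGC-27 may come from GC-dependent loss in the control. It lies at percentile 64.9 among 499 genes of similar GC content and abundance, whose changes had a median of 1.43 and a central 95% from -0.37 to 4.11. In AGS the fall lies at percentile 10.0 of the same genes, whose median was -0.03, and whether the overexpression took hold in either line stays open, also because the labels do not say whether the counted sequence is in the lentivirus.

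The last pattern is that the NINJ1 replicate 2 libraries lie with the other line than their titles say. Exchanged files are a candidate explanation. Against the NINJ1 replicate 1 libraries, both correlated more with the line in the file name, by 0.0416 and 0.0464 in r. Against the controls, on GC-corrected log2 CPM, they did so by 0.0806 and 0.0275. On log2(FPKM + 1) without the correction the differences were 0.117 and -0.0673, so the measure changed along with the correction. On that measure HGC-27 NINJ1 replicate 1 itself lay closer to the AGS control. In the 15 and 13 genes that separate the 4 undisputed libraries, the share of genes seen in a replicate 2 library was 100 percentage points higher for the line in the file name than for the line in the title, for both libraries. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05: the file-name split gave 1082 genes and the highest other 0 (1 of 10 splits as large), and the split by titles gave 0 with 1082 as the highest other (10 of 10 as large). How the titles came to differ from the file names stays open, and no biological explanation was tested.

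The other differences between the lines were in single genes, several with few counts, given as fitted log2 values that depend on the prior count and are no bounds. Counts are in the order control, NINJ1 replicate 1 and replicate 2 with the file-name lines. The processed pseudogenes HSPA8P8 (11.06; HGC-27 29, 1 and 0, AGS 0, 6 and 4), ANKRD26P4 (9.96; 19, 0 and 1 against 0, 5 and 2) and RLIMP1 (9.48; 21, 3 and 0 against 0, 3 and 9) had a higher change in AGS. So had SORCS1 (9.35; 10, 1 and 2 against 0, 11 and 12). ACVRL1, an endothelial receptor (-13.01; 0, 10 and 23 against 8, 0 and 0), CTXN1 (-12.31; 0, 214 and 249 against 290, 96 and 94), LRFN1 (-11.84; 0, 60 and 46 against 1, 0 and 0) and PLXNB3 (-11.71; 0, 197 and 224 against 215, 114 and 80) had a lower one. For LRFN1 the call ended with the GC correction (edgeR adjusted p = 0.0687), while the difference stayed about as large (-11.21). CTXN1, LRFN1 and PLXNB3 have a GC content of 72.8%, 66.5% and 65.1%, the class in which the HGC-27 control lay lowest.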

How the results depend on the processing

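The GC correction, limma on unscaled log2(FPKM + 1), the block with crossed numbers and the list tests within lines were chosen after the results were seen. The other alternatives were chosen in advance. Counts below are genes past the threshold, and the cause of a difference was not tested unless named.

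With DESeq2 in place of edgeR, 312 genes passed over both lines, 1308 in AGS and 2459 between the lines by file names. By titles 53 passed over both lines, 4160 in HGC-27, 27 in AGS and 2203 for the difference, and 4 passed in the 4 undisputed libraries. Without a filter the title counts were 37, 3949, 1 and 1993, and 8 lists were called in HGC-27. With a mean FPKM of at least 5, which leaves fewer genes to test, 5991 passed in HGC-27, 1550 in AGS, 5473 for the difference and 233 between the lines (file names), 641 for the difference (titles), and 3 lists in HGC-27.

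With limma, AGS by file names had 950 genes without rescaling, 793 and 908 with pseudocounts of 0.1 and 0.5, 1749 rescaled to equal sums, 947 divided by size factors and 938 under quantile normalisation. The undisputed libraries had 0, 0, 0, 0, 3 and 21. The difference by titles had 987, 379 and 650 with the pseudocounts and equal sums. Quantile normalisation gave 120 genes in HGC-27 by titles and 5 lists over both lines under either reading. NINJ1 in AGS no longer passed, at log2 -0.70 with DESeq2 (adjusted p = 0.136) and, in the order above, -0.57, -0.63, -0.60, -0.50, -0.64 and -0.65 with limma (adjusted p from 0.0587 to 0.0884).

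With the GC correction 0 genes passed in HGC-27 by titles, 327 over both lines, 6226 for the difference and 3866 between the lines by file names, with 15 lists in HGC-27 and NINJ1 at log2 -0.066 over both lines. It turned the sign in HGC-27 for TNFAIP2 (-0.014), HLA-C (-0.53), CDT1 (-0.36), KRT7 (-0.99), ESRP2 (-0.26), LAMA5 (-0.048), MMP15 (-0.86), LTBP3 (-0.58), FASN (-0.59) and H1F0 (-0.051). Lists with an estimated correlation were 0 for both readings over both lines, 0 in HGC-27 and 0 in AGS. Fry called 0 (titles), 3 (file names), 13 and 8.

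Replicate numbers showed no pairing by file names, where the check of shared deviations gave 0.00841. By titles it gave -0.811, which cannot speak to pairing. Each titled pair holds 1 library of each line profile, so the line difference itself sets that value. A replicate block, by replicate number, was fitted to the 4 NINJ1 libraries alone, without the controls. There 7188 genes differed between the lines by file names (3659 higher in AGS, 3529 lower) and 0 by titles (9 with the numbers crossed). The rise from 1082 by file names cannot be credited to the block, since the controls were left out as well.

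Leaving out 1 library at a time assumes that a lone library varies like the other groups, and without a control the comparison over both lines is that of 1 line. Gene counts by titles ran from 0 to 2209 over both lines, 0 to 2209 in HGC-27, and were 0 in AGS, for the difference and between the lines. By file names they ran from 0 to 11043 over both lines, 10704 to 11321 in HGC-27, 935 to 4712 in AGS, 8417 to 10372 for the difference and 114 to 7117 between the lines. Lists ran from 3 to 15 (titles) and 5 to 16 (file names) over both lines, 4 to 5 in HGC-27 and 16 to 17 in AGS. NINJ1 ran from -0.68 to 1.95 over both lines, 1.81 to 1.95 in HGC-27 and -0.83 to -0.54 in AGS.

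Over all alternatives, values of the named genes other than NINJ1 kept direction and side of the threshold in 3581 cases by file names, passed newly in 86, no longer passed in 250 and turned sign in 10. By titles the numbers were 347, 53, 48 and 0. NINJ1 also turned sign: over both lines with the GC correction (-0.066 by file names, -0.037 by titles) and without the HGC-27 control (-0.68 and -0.55), and between the lines by file names without either control (-0.037 and -0.035) and with the replicate block (-0.032). The smaller-difference check of lines against controls was 0.117 and -0.0673 (Spearman 0.138 and -0.0635). Depth limits genes with few counts: a count of 0 allows a mean of up to 3.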

Other observations

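The test in this part was written before its result was seen. The hypothesis was that both lines share a response to NINJ1 that the GC profile of the HGC-27 control hides. After the GC correction, 611 genes were higher in both lines where independent calls would give 342 (ratio 1.79), and 909 were lower in both where they would give 474 (ratio 1.92). Genes going opposite ways numbered 271 and 366, against 409 and 396. Without the correction the counts were 350 against 343 (ratio 1.02) and 493 against 476 (ratio 1.04), with 720 and 349 in opposite directions against 556 and 293, and the log2 changes of the 2 lines had r = -0.0226 across all tested genes (0.0669 after the correction). The 2 contrasts use different controls, so the overlap is not built in by a common library. Both come from 1 model with a shared spread per gene, so genes with a small spread are called more readily in both lines. Independent calls may therefore be too low a baseline, and without the correction the opposite directions exceeded it too. A shared response may exist for some genes with the correction, but NINJ1 level was below control in the NINJ1-labelled AGS libraries. Any other difference between NINJ1 and control libraries that recurs in both lines, such as a batch, could give the same overlap.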
